A study of Drosophila melanogaster with 2 samples.

How the data were processed

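Chromatin from whole embryos of mixed sex, 0 to 24 hours old, carrying Dp fused to green fluorescent protein was sheared by sonication to between 200 and 800 bp, per the labels' protocols. The series has 1 group with 2 biological replicates, numbered 1 and 3 in the labels. Nothing in the labels says whether they came from separate cultures beyond that, so measures of error reflect the spread between these samples, which may be technical in part.

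The authors deposited a relaxed peak list for each replicate, a relaxed list for both replicates pooled, and a list thresholded by irreproducible discovery rate (IDR), all on dm6 per the file headers. Per the descriptions deposited with the files, each list was called on alignments against the same separate control alignment, and the thresholded list was derived from both replicate lists and the pooled one. The aligner, the peak caller and their versions are not given in the sources used here. The signal value of each peak is the authors' own, as deposited; its scale is not stated, so it was used to rank and describe peaks within a list, and fold values are ratios of it within the thresholded list. The −log10 q of each peak, as deposited, reached a single highest value of 4.30 in all 5828 thresholded peaks and was not used to rank them. The summit offset, counted in bases from the peak start, was also deposited by the authors and gave the positions used here. All 5828 thresholded peaks were in the pooled list, and they were the 5828 pooled peaks with the highest signal value. Chromosome names and lengths of the reference dm6 genome held every peak, and genes came from the Ensembl release 115 annotation of the same assembly. Only protein-coding genes were used, so starts, introns and intergenic sequence refer to these genes alone. A summit at a noncoding gene can therefore be counted as intergenic and far from a start. Coordinates are 1-based.

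Peaks on the 6 main arms, 2L, 2R, 3L, 3R, 4 and X, were used. A gene was called bound when a thresholded summit lay within 500 bp of any of its annotated starts, and its value was that of the strongest such peak. Replicate lists were compared by an overlap of at least 1 bp between the 5828 peaks of highest signal in each, against 100 shuffles of positions on the same arm. The signal of a replicate at a thresholded peak was that of its relaxed peak nearest the summit. Motifs were searched on both strands within 100 bp of the summit and, as a comparison, within 100 bp of the points 500 bp to either side; the exact McNemar p printed is the larger of those for the 2 sides, adjusted by Benjamini-Hochberg over 10 motifs. Gene lists, 17 in all, were compared with all other protein-coding genes by two-sided Fisher's exact tests, and the median log2 signal of lists with at least 5 bound genes was compared with random draws of bound genes in a two-sided permutation test (100000 resamples, so that 1e-05 is the smallest p). Both were adjusted by Benjamini-Hochberg, over 17 and 14 lists. The draws of the permutation test were made with replacement from all bound genes, the list's own included. Medians were scored by their distance from the median of all bound genes. Printed fold values and log2 differences compare a list with the other bound genes. Intervals of shares are exact binomial at 95%, and genes and peaks were treated as independent units, which they are not in full. Of the germline list 23 of 24 members were matched to the annotation. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

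Gene lists, motifs, tests, main settings, the alternatives to be tried and the rule for naming genes were fixed before the data were examined. The rule named 13 regulators whatever their values, the 4 bound members with the highest signal in each list with at least 5 bound genes, and the genes nearest the 10 strongest peaks; some of these are not reported here. Alternatives changed the distance to the start, the motif window, the overlap, the number of peaks, the value per gene, the assignment of peaks to genes and the background, or used the 5828 strongest peaks of a single replicate. The tests were tried on simulated data; a smaller first simulation of the signal test called fewer planted lists than the target set for it, and it was enlarged, with its criteria set again, without a change to the test. The list test called 20 of 20 planted lists and 0 of 20 unchanged ones over 13945 genes, the signal test called 95.3% of lists raised by 1.0 on the log2 scale and gave an unadjusted p under 0.05 in 5.60% of unchanged lists over 6325 simulated genes, and the motif test called 100 of 100 simulations with a doubled share and 0 of 100 with equal shares over 5828 peaks. The raised lists of the signal test were of equal size and were adjusted together, with no unchanged list among them. The share called there therefore does not carry over to the real lists, least of all to small ones.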

Results

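Binding of Dp, the dimerization partner with which the E2F transcription factors contact DNA, was mapped by ChIP-seq in whole Drosophila melanogaster embryos collected over 0 to 24 hours of development. Embryos of both sexes came from a transgenic line in which green fluorescent protein was fused to the carboxyl end of Dp, and 2 biological replicates, numbered 1 and 3 by the labels, formed the only group. The design therefore held no contrast between conditions, and the questions it allowed were where Dp was found, in which genes, and how far the replicates matched. The thresholded list held 5828 summits in 5134 intervals with a median width of 543 bp on the dm6 assembly, and each replicate had a relaxed list of 30000 peaks. Read depth was unknown, since the files give peaks and not reads. The labels describe the libraries as input controls while naming Dp as the target, and the 2 statements were not reconciled.

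Dp occupied largely the same places in the replicates. Among the 5828 peaks with the highest signal in replicate 1, 91.8% overlapped a peak of the same rank range in replicate 3, and 97.9% did so in the opposite direction, where shuffled positions gave a mean of 4.15% and a highest value of 4.91% (permutation of positions, p = 0.0099, the smallest that 100 shuffles can give). Of the thresholded peaks, 5387 (92.4%) lay in the top lists of both replicates, 328 in that of replicate 1 alone and 80 in that of replicate 3 alone. Across the 5817 peaks with a value in both replicates, signal values had a Spearman correlation of 0.939 (95% bootstrap interval 0.933 to 0.945) and a Pearson r of 0.942 on the log2 scale; peaks are not independent replicates. The log2 difference of replicate 3 minus replicate 1 had a median of -0.18 and a standard deviation of 0.48, which is a spread of 1.40-fold between replicates for a single peak. Both lists were called against the same control, so part of the overlap could be shared through it. The thresholded peaks were themselves selected for reproducibility from these lists and have the highest pooled signal, so their presence in both top lists and the correlations over them are set in part by that selection.

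Dp lay mainly at promoters. Summits within 500 bp of an annotated transcription start numbered 5107, or 87.6%, against a mean of 12.7% and a highest value of 14% for positions shuffled on the same arms (permutation of positions, p = 0.0099, the smallest that 100 shuffles can give). The median distance from summit to start was 67 bp. Of the peaks further away, 353 were intergenic with respect to protein-coding genes, 290 lay in introns, 51 in 3′ untranslated regions, 17 in coding exons and 10 in 5′ untranslated regions. Of all peaks, 322 were more than 2000 bp from any start of a protein-coding gene. Starts of noncoding genes were not considered.

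The E2F core sequence TTSSCGC, the site that E2F and Dp dimers bind, was found within 100 bp of 1103 summits. That was 18.9% of them, against 10.2% of flanks 500 bp away, a ratio of 1.85 (two-sided exact McNemar test, adjusted p = 9.94e-41 over 10 motifs). Most summits lay at promoters, so sequences placed there can exceed the flanks whether or not Dp binds them. The longer form TTTSSCGC gave 10.2% against 3.43% (exact McNemar test, adjusted p = 1.93e-46). The CHR element TTYGAA, a site of MuvB complexes at cell cycle promoters, was at 49.3% of summits and 21.8% of flanks (exact McNemar test, adjusted p = 3.94e-194). The DRE and core promoter motif 1, elements of ubiquitously active promoters, stood out most against the flanks. The DRE sequence TATCGATA, bound by the factor DREF, was at 14.5% against 0.721% (exact McNemar test, adjusted p = 2.72e-198), its CGATA part at 51.0% against 22.2% (adjusted p = 1.05e-213), and motif 1, bound by M1BP, at 7.02% against 0.257% (adjusted p = 2.44e-99). The Myb site YAACKG was at 32% against 26.9% (exact McNemar test, adjusted p = 2.49e-08). Sites of the early zygotic activator Zelda were rarer at summits, at 0.806% against 1.54% (exact McNemar test, adjusted p = 0.0141), and neither GAGA factor sites, at 2.54% against 2.80% (adjusted p = 0.706), nor E-boxes, at 3.05% against 3.00% (adjusted p = 1), passed the test.

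The E2F core and CHR were most frequent in the strongest peaks. The 582 strongest peaks carried the E2F core in 42.3% (95% exact interval 38.2% to 46.4%) and CHR in 71.8% (68.0% to 75.4%), while the 583 weakest carried them in 15.1% (12.3% to 18.3%) and 33.8% (30% to 37.8%). With the peaks in 10 bins by strength, the E2F share was between 11.5% and 12.5% from the fifth bin to the ninth. DRE fell from 21.3% (18.0% to 24.9%) to 5.15% (3.50% to 7.26%). GAGA factor sites went the other way, from 1.55% (0.709% to 2.92%) to 5.49% (3.78% to 7.66%). The Myb site stood at 29.7% and 29.5%, with intervals of 26.0% to 33.6% and 25.8% to 33.4%.

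**Figure D1:**
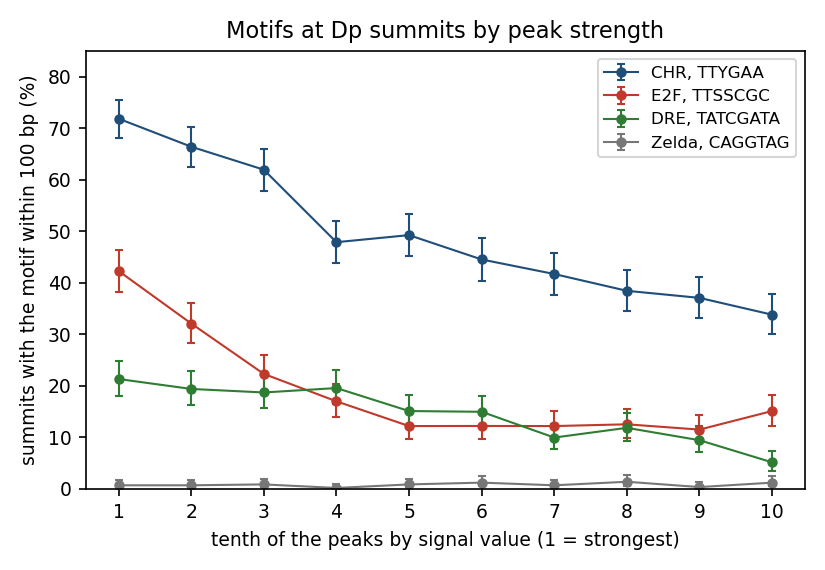
Share of summits (%) with each motif within 100 bp, for 10 bins of the thresholded peaks ordered by signal value from strongest to weakest, with 95% exact binomial intervals. The E2F core goes from 42.3% in the strongest peaks to between 11.5% and 12.5% in the fifth to ninth bins and 15.1% in the weakest, CHR falls from 71.8% to 33.8% and DRE from 21.3% to 5.15%, while the Zelda site stays under 2%.

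Genes that run the cell cycle were bound almost without exception. A Dp summit lay within 500 bp of a start for 47 of 48 mitosis genes, 40 of 42 DNA replication genes, all 30 DNA repair and checkpoint genes, 20 of 22 genes of G1/S control and the DREAM complex, and 17 of 19 chromatin assembly genes, where 5891 of all 13945 protein-coding genes (42.2%) were bound. Nucleotide synthesis followed with 13 of 17. Each list exceeded the other genes in Fisher's exact test, with adjusted p over 17 lists of 3.71e-16 for mitosis, 8.43e-13 for replication, 1.38e-11 for repair, 5.28e-06 for G1/S control, 4.11e-05 for chromatin assembly and 0.00686 for nucleotide synthesis. Exceptions in these lists included Psf1 and RPA1 in replication, Klp61F, a kinesin of the spindle, in mitosis, Cdk4 and stg in G1/S control, Nipped-B, the cohesin loader, and vtd, a cohesin subunit, in chromatin assembly, and Dhod, Gart and Paics in nucleotide synthesis. These exceptions are named after their values were seen, apart from stg. Against only the 7852 genes with a relaxed peak of both replicates at a start, of which 74.8% were bound, the G1/S list (Fisher's exact test, adjusted p = 0.158) and nucleotide synthesis (adjusted p = 1) no longer passed.

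The genes of the E2F and DREAM machinery were themselves bound. The peak at Dp ran from 13222022 to 13222929 on arm 2R, with its summit in the 5′ untranslated region 23 bp from the start, a signal value of 4853 and replicate values of 2850 in replicate 1 and 2056 in replicate 3; an E2F site, TTGGCGC, lay from 13222441 to 13222447. E2f1, the activating E2F, had an intergenic summit 184 bp from its start, in a peak on 3R from 21660705 to 21661381 with a signal of 2782. E2f2, the repressive E2F, had a peak on 2L from 21155849 to 21157142 with a signal of 1863 and its summit in the 5′ untranslated region, and Rbf, the retinoblastoma protein that binds E2Fs, had one on X from 800878 to 802150 with a signal of 3159. The peak of mip120, a MuvB subunit, was in an intron 57 bp from an annotated start on 2R, from 13509136 to 13510035, and at 7578 it ranked 38 of all peaks. Myb, which joins that complex, was bound far more weakly, at 271 and rank 5120, on X from 15857627 to 15857992. The cyclins of S phase and mitosis were strong, with 8344 for CycA on 3L from 11833068 to 11834015 and 3473 for CycE on 2L from 15747146 to 15748840. E2f2 and CycE, like Dp, had 1 E2F core within 100 bp of the summit, while E2f1, Rbf, mip120, Myb and CycA had none. The phosphatase gene stg, the rate-limiting activator of mitosis in the embryo, had no summit closer than 3635 bp to a start.

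Replication origin and fork genes carried some of the strongest of these peaks. PolE2 and PolE1, subunits of DNA polymerase epsilon, had signal values of 7560 on 3L from 5896981 to 5897905 and 7139 on 3R from 23347616 to 23348538, and Cdc6 and dup, which load the replicative helicase, had 7185 on 3L from 8633612 to 8634533 and 5632 on 2R from 15380250 to 15381245. Orc1 had 4455, PCNA 2206, Mcm2 1572, and RnrL and RnrS, the ribonucleotide reductase subunits, 1514 and 1475. The PCNA summit, on 2R from 20262525 to 20263341, had a DRE and no E2F core within 100 bp, while Orc1, RnrL and RnrS each had 2 E2F sites and PolE1 had 3. In mitosis the highest values were 10090 for mad2, of the spindle checkpoint, 6611 for CycB3, 5786 for borr, of the chromosomal passenger complex, and 5323 for cal1, which loads the centromeric histone. In repair high values were 7123 for FANCI, 3537 for tos and 3178 for phr. In chromatin assembly dmt and dre4, among the 4 with the highest signal, had 2358 and 2047.

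Housekeeping genes were also bound widely. A summit was present for 74 of 92 cytoplasmic and 63 of 73 mitochondrial ribosomal protein genes (adjusted p = 2.50e-13 and 4.97e-14), 58 of 86 oxidative phosphorylation genes (adjusted p = 5.28e-06) and 32 of 48 proteasome genes (adjusted p = 0.00148), all by Fisher's exact test. Together they were bound in 227 of 299 (75.9%), against 150 of 159 (94.3%) for replication, nucleotide synthesis, G1/S control, mitosis and repair together, a difference of 18.4 percentage points (two-sided Fisher's exact test, p = 2.91e-07). RpS29 led the cytoplasmic ribosomal genes at 6649, mRpL38 the mitochondrial ones at 3080, Prosbeta2R2 the proteasome at 4670 and COX4 oxidative phosphorylation at 5208. Leaving out 14 cytoplasmic ribosomal, 16 proteasome and 22 oxidative phosphorylation members whose symbol marks a paralog, an alternative chosen after seeing the data, brought the difference to 8.51 points (Fisher's exact test, p = 0.00830). Among genes with a relaxed peak of both replicates at a start, also chosen after seeing the data, it was 5.47 points, 149 of 156 against 226 of 251, and no longer passed (Fisher's exact test, p = 0.0574). That background was picked by signal from the same libraries and held 5875 of the 5891 bound genes. It leaves out mainly unbound genes, so the narrowing is in part built in. The difference was 31.8 points with each summit given only to its nearest start, also chosen after seeing the data, and 42.1 points with the 2914 strongest peaks alone.

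Genes of embryo patterning and of differentiated tissues mostly had no thresholded Dp summit at a start. Some of the unbound ones had weaker peaks. Among members with a relaxed peak of both replicates at a start, 50% of chemoreceptor, 38.5% of neuronal and 30.8% of patterning genes were bound. The shares were 30% for cuticle and 22.2% for muscle genes. Bound members numbered 8 of 230 chemoreceptor and odorant-binding genes (3.48%, adjusted p = 2.14e-41), 3 of 116 cuticle protein genes (adjusted p = 2.16e-22), 4 of 43 embryo patterning genes (adjusted p = 5.29e-06), 2 of 21 muscle genes (adjusted p = 0.00209) and 5 of 24 neuronal genes (adjusted p = 0.0405), each below the other genes in Fisher's exact test. In the patterning list bcd, the anterior morphogen, had 1289, sog 656, Scr 478 and tin 216. The muscle members were Tm1, a tropomyosin, at 5037 and sls at 223, and the cuticle members Lcp9, Lcp2 and Lcp3. These patterning, muscle and cuticle names were chosen after their values were seen. The neuronal genes with the highest values were eag, a potassium channel, at 1302, nSyb at 599, elav at 468 and brp at 432. Germline and piRNA genes were bound in 15 of 23 (Fisher's exact test, adjusted p = 0.0377), among them tej at 12251, bam at 5433, bgcn at 3113 and krimp at 2687. The summits counted for tej and bam lay 489 and 494 bp from their starts, close to the limit of 500 bp. Apoptosis genes, at 8 of 13, did not pass (Fisher's exact test, adjusted p = 0.172); the caspase gene Dcp-1 had 4449, Buffy 4124, Diap1 2484 and Dronc 845, the members without a summit at a start, named after this was seen, were rpr, hid, grim, skl and Dark.

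Calls for the germline and neuronal lists were lost under several settings. The germline share went to 56.5% without replicate 1 (Fisher's exact test, adjusted p = 0.146) and to 39.1% with nearest starts only (adjusted p = 0.505), and the neuronal list missed the threshold without replicate 1 (20.8%, Fisher's exact test, adjusted p = 0.0684). The muscle share went from 9.52% to 4.76% without replicate 1 and 14.3% without replicate 3, and passed in both. Neighbouring genes often shared a promoter peak: 3372 of the 5891 bound genes (57.2%) had a strongest peak that also served another gene.

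**Figure D2:**
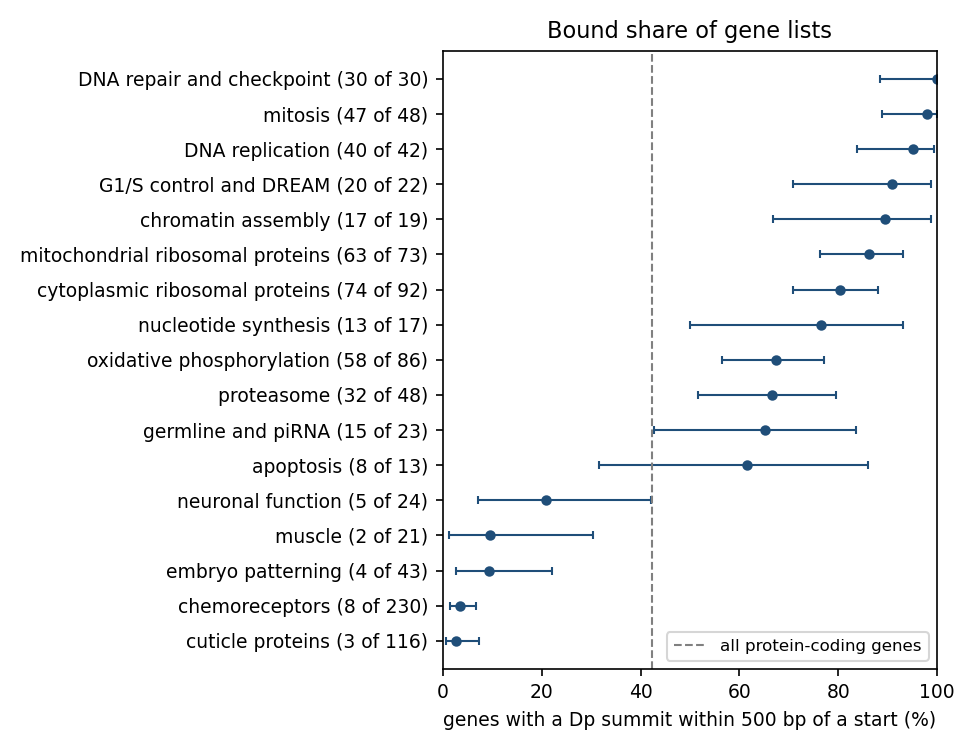
Share of each gene list (%) with a thresholded Dp summit within 500 bp of a transcription start, as points with 95% exact binomial intervals and the number of genes beside each name; the dashed line marks all protein-coding genes, 42.2%. The cell cycle lists sit at the upper end, with 47 of 48 mitosis genes, and the chemoreceptor and cuticle lists at the lower, with 8 of 230 and 3 of 116.

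Among bound genes, those of mitosis and replication had the stronger peaks. The median signal of the 47 bound mitosis genes was 2295, or 3.15-fold that of other bound genes, and the 40 bound replication genes reached 2075, or 2.84-fold (permutation test, adjusted p = 0.00014 and 0.00021 over 14 lists). G1/S control genes stood at 2.33-fold (permutation test, adjusted p = 0.0420) and repair genes at 1.84-fold (permutation test, adjusted p = 0.0494). Nucleotide synthesis (2.06-fold), chemoreceptor (1.64-fold), germline (1.32-fold), chromatin assembly (1.19-fold), oxidative phosphorylation (1.11-fold), apoptosis (1.06-fold), cytoplasmic ribosomal (1.05-fold), proteasome (0.971-fold), mitochondrial ribosomal (0.802-fold) and neuronal genes (0.636-fold) did not pass, with adjusted p from 0.153 to 0.885 in the permutation test. Without replicate 1 the G1/S and repair calls were lost (permutation test, adjusted p = 0.0847 and 0.0924), and without replicate 3 the chemoreceptor genes passed, with a log2 difference of 2.58 (permutation test, adjusted p = 0.00201). The germline log2 difference went from 0.40 to 1.27 without replicate 1 and still missed the threshold (permutation test, adjusted p = 0.0847). Within the 2914 strongest peaks, mitosis (log2 difference 0.65, permutation test, adjusted p = 0.0555) and replication (0.45, permutation test, adjusted p = 0.262) did not pass either.

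Of the genes nearest the 10 strongest peaks, mad2 alone was a member of the cell cycle lists. Of these 10, 9 are described here. Ranks 2 and 3 were a peak 489 bp from tej, of the piRNA pathway, on 2R from 14302228 to 14303322, and an intergenic one 3395 bp from slbo, the C/EBP factor of border cells, on 2R from 24337193 to 24338092, at 12251 and 11972. Those nearest Nepl8, ftz-f1, mad2, CG9630, vig, Meltrin and Syx7 had values of 11871, 10200, 10090, 9859, 9780, 9706 and 9463. The peak at vig had its summit in an intron and the other peaks named here in intergenic sequence.

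Peaks were spread over the arms nearly as genes were, with the X somewhat richer and chromosome 4 poorer. The X held 1027 peaks, 17.6% of them against 15.7% of protein-coding genes, a ratio of 1.12, and chromosome 4 held 24, a ratio of 0.718. The ratios on 2L, 2R, 3L and 3R were 0.961, 1.00, 0.971 and 0.981, and the chi-square test over the 6 arms gave 18.9 (p = 0.00200), with peaks counted as independent.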

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

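The tests of E2F sites and the first test of open promoters were set before the data were examined, and the other tests of open promoters and those of the peaks outside the thresholded list were chosen after those results were seen.

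The pooled relaxed list held 4169 further peaks at the same highest −log10 q as the thresholded ones but outside that list, with signal values of 81.3 to 213; the comparisons of the report rest on the thresholded list and leave them out. Side summits of thresholded peaks would lie beside them, and 24.5% were within 500 bp of a thresholded summit, which argues against that source for most. Chance positions would lack promoters and motifs, but 56.4% of all of them, and 46.0% of the 3146 further than 500 bp from a thresholded summit, lay within 500 bp of a start, where the highest of 100 shuffles of the whole set gave 14.1%, and the DRE was 5.27 times as frequent at their summits as at flanks (exact McNemar test, p = 3.17e-15). The E2F core was at 13.5% of these summits and 8.94% of flanks (exact McNemar test, p = 6.78e-10), CHR at 33.0% and 26.2% (exact McNemar test, p = 1.27e-11) and GAGA factor sites at 8.20% and 4.04% (exact McNemar test, p = 6.53e-14). Binding that falls below the threshold is one hypothesis; no biological explanation was tested, and open chromatin of any kind remains possible.

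The share of E2F sites at summits could have come from input chromatin, as the sample descriptions word it, or from base composition. Input with no Dp enrichment would give a summit share near that of the flanks, and the ratio was 1.85, although open promoters in input might also be called, so this bears on the label only in part. Of 629 other orders of the same letters, 0 had a ratio as high, and the highest was 1.61, which argues against base composition as the whole source. That the sites reflect binding of the E2F and Dp dimer is a hypothesis, and how many peaks came through other factors on the same promoters stays open.

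The bound share of cell cycle genes could follow from open promoters being called whatever they hold. Cell cycle lists exceeded housekeeping lists, which also have active promoters, by 18.4 points, and by 8.51 points without paralogs (Fisher's exact test, p = 0.00830). A relaxed peak in both replicates was present for 251 of the 299 housekeeping genes and 156 of the 159 cell cycle genes. These peaks come from the same Dp libraries, and 5875 of the 5891 bound genes had one. Keeping only such genes thus leaves out mainly unbound genes, tends to narrow the difference and does not measure how open a promoter is. Among genes with such a peak the difference was 5.47 points (Fisher's exact test, p = 0.0574), and that comparison by itself does not decide the matter. Without paralogs 93.8% of proteasome genes were bound, against 94.3% for the cell cycle lists. The other housekeeping lists were lower in that setting. They stood at 83.3% for cytoplasmic ribosomal, 86.3% for mitochondrial ribosomal and 84.4% for oxidative phosphorylation genes. The difference between all cell cycle and all housekeeping genes was 22.4 points within 200 bp of a start and 16.3 within 1000 bp. It was 31.8 points with nearest starts only. That setting gives each summit to a single gene and takes calls from genes that share a promoter peak, so it does not bear on how open promoters were. At each of the distances, and in the 18.4 points within 500 bp, housekeeping genes, paralogs included, were bound less often than cell cycle genes. Promoters equally open and called whatever they hold would give equal shares. Proteasome genes without paralogs are an exception to the difference, being bound nearly as often as the cell cycle lists. No accessibility data were used here, and the lists may differ in how open their promoters are. These values thus do not decide whether open promoters of any kind are the whole source of the difference.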

How the results depend on the processing

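Of 204 alternatives to 37 results, 178 kept the direction and the side of the threshold, 18 lost the call, 1 gained it, 6 changed sign and 1 moved beyond its interval; 5 on paralogs, 1 on nearest starts and 1 on background genes were chosen after seeing the data. With genes holding a relaxed peak in both replicates as background, nucleotide synthesis (76.5%), G1/S control (90.5%), germline (87.5%) and the difference between cell cycle and housekeeping lists (5.47 points) lost their calls. Of that background, itself picked by Dp signal, 74.8% was bound. The germline list also lost its call within 200 bp (47.8%) and with nearest starts only (39.1%), and the neuronal list within 1000 bp (25%) and with nearest starts (20.8%); the cause was not tested. Leaving out a replicate gave 56.5% to 65.2% for germline and 20.8% both ways for the neuronal list. In the 2914 strongest peaks, which holds fewer genes over a narrower range, log2 signal differences fell below the threshold for replication (0.45), G1/S control (0.27), mitosis (0.65) and repair (0.10), and with ranks for G1/S control (1239 ranks) and repair (969.5 ranks). The 6 changes of sign were in log2 signal differences that passed the threshold in neither setting: with the 2914 strongest peaks chromatin assembly went to -0.33, apoptosis to -0.085, cytoplasmic ribosomal genes to -0.13 and oxidative phosphorylation to -0.64, and leaving out a replicate gave -0.030 to 0.15 for apoptosis and -0.0046 to 0.10 for cytoplasmic ribosomal genes. Without replicate 1 or 3 the log2 differences were 1.03 to 1.21 for G1/S control, 0.73 to 0.92 for repair, 0.51 to 1.27 for germline, against 0.40 with both, and 0.53 to 2.58 for chemoreceptors; the cause was not tested. The replicate Spearman correlation was 0.962 in the strongest 2914. No signal test was possible there for chemoreceptor and neuronal genes, with fewer than 5 bound. Depth limits weak peaks, and its size is unknown.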

Other observations

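The tests in this part were all chosen after the patterns had been seen, so each explanation is a hypothesis found in the same data.

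Replication and mitosis promoters, the cell cycle lists with the highest and the lowest E2F share, may differ in the sequences under their Dp peaks. The E2F core was at 24 of 40 replication peaks (60.0%) and 8 of 47 mitosis peaks (17.0%), where all 4153 promoter peaks that were the strongest of a gene had 19.4% (two-sided Fisher's exact test, p = 4.7e-05, adjusted p = 0.000141 over 3 motifs). The CHR element was at 42.5% and 57.4% (Fisher's exact test, adjusted p = 0.2) and core promoter motif 1 at 10% and 25.5% (Fisher's exact test, adjusted p = 0.142), neither past the threshold. The 4153 promoter peaks had CHR at 50.8% and motif 1 at 8.86%. Of the cell cycle lists only mitosis lay above that CHR share, and oxidative phosphorylation peaks had CHR at 53.4%. The E2F difference stood at p = 0.000470 in Fisher's exact test multiplied by the 10 pairs that the 5 cell cycle lists form, and no other pair passed. Repair peaks had the E2F core in 43.3% and cytoplasmic ribosomal ones in 14.9%. Why the E2F shares differ was not tested.

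Strong peaks away from promoters of protein-coding genes also held E2F and CHR sites. Of the 582 strongest peaks, 64 lay more than 500 bp from any annotated start of a protein-coding gene, and the E2F core was at 42.2% of them and CHR at 76.6%, against 42.3% and 71.2% of the 518 at promoters (Fisher's exact test, adjusted p = 1 and 0.692 over 3 motifs). DRE was at 14.1% against 22.2% (Fisher's exact test, adjusted p = 0.443) and the Zelda site, not tested, at 3.13% against 0.386%. With 64 peaks these tests do not show that the sets are alike. Among the strongest peaks E2F sites lay at a median of 42 bp from the summit, CHR at 54.5 bp and DRE at 25.5 bp, where even scatter over the searched window would give 49 bp, 49 bp and 48.5 bp.

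The E2F core and CHR may sit at fixed spacings. In the 1000 strongest peaks, where the pattern was noticed, CHR began 7 bases before or 11 or 12 bases after the start of TTSSCGC, read on its strand, in 74 pairs. In the other 4828 peaks the same offsets held 37 pairs, against a mean of 7.65 and a highest value of 14 when motifs were paired across peaks 100 times. Of the 37, 18 were at the offset before the E2F core, 10 at 11 bases and 9 at 12, while another offset also reached 9, so the first stands clear and the other two do not by themselves. Copies of 1 sequence at several promoters were not excluded. Nor were pairs counted again at neighbouring summits, of which 5828 lay in 5134 intervals. Such repeats can also fall in both sets of peaks, so the weaker peaks are not a fully separate check.

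The region around Dp could hold extra copies in the transgenic line. Within 20 kb of the gene there were 11 thresholded peaks and 36 relaxed ones, a number above 96.6% of 1000 windows at other genes. The windows were not matched for the number of gene starts, so the count alone does not point to extra copies. Of the 11, 5 were among the 582 strongest peaks. The median signal of the relaxed peaks stood at percentile 70.8, which does not decide the matter, since extra copies could also bring weak peaks into the list and lower that median. The explanation stays open.

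Peaks at chemoreceptor genes may belong to their neighbours. Of the 8 bound genes of that list, 6 had a peak nearer to the start of another gene, among them Gr63a, Ir60e, Obp47b and Obp93a, whose peaks of 6190, 6202, 5588 and 4138 lay 26 to 50 bp from the starts of Lamtor4, CG13585, CG7741 and Ice2 and 247 to 479 bp from their own.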
